A study of Mus musculus with 6 samples.

How the data were processed

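RNA of mouse cumulus granulosa cells, the somatic cells around the oocyte, was measured by sequencing in 6 libraries. Of these, 3 were labelled control (numbers 2, 3 and 4) and 3 were labelled Atg5-KD (numbers 2, 3 and 4), for cells given short hairpin RNAs against Atg5. Per the labels' protocols, the molecule was poly(A) RNA, the input was total RNA with no selection step described, libraries were made with a NEBNext Ultra kit, and read pairs were sequenced on a HiSeq X-Ten or a NovaSeq instrument. The same protocol text also describes amplified cDNA and a TruePrep kit, and which of these applied to which library is not given in the sources used here, nor are the strandedness of the kit, the annotation used for counting, or what the control cells received. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the Wald p-values of single genes measure the spread between these libraries, which may be technical.

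The submitters' processing notes name STAR, featureCounts 1.6.2, StringTie 2.1.4, DESeq2 1.30.1 and the mouse build mm10, with no role or order. A single table was used here, the authors' own comparison of both groups, with the column names of a DESeq2 results table per the file headers. Its base mean is a signal value made by the authors, the mean over libraries of read counts divided by size factors. Its log2 fold change and standard error are on the log2 scale and were computed by the authors. Its Wald statistic is a score deposited by the authors. Its p-value and adjusted p-value columns were also deposited by the authors. The table has 24982 rows, of which 5741 have a base mean of 0, 19241 have a p-value and 14835 have an adjusted p-value. The 4406 rows with a p-value and no adjusted p-value all have a base mean of at most 3.30, and the lowest base mean with an adjusted p-value is 3.31. The statistic was checked to equal the log2 fold change over its standard error, the p-value to be the two-sided normal p of the statistic and the adjusted p-value to be its Benjamini-Hochberg adjustment over the 14835 rows, and 0 rows differed at a tolerance of 1e-06. The table pools the libraries, and 0 columns hold values per library.

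The direction of the fold change is not written in the columns. It was read from the order of both groups in the table's name as Atg5-KD over control, and the target gene gives no check of it as deposited because its fold change is close to 0. Every statement of higher or lower therefore refers to the libraries labelled Atg5-KD as that order gives them.

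The quasi-likelihood test planned for read counts before the data were examined could not be run without values per library. The plan's branch for a table of comparisons was followed for single genes, and the list test departed from it as given below. A gene was called higher or lower when the deposited adjusted p was under 0.05, with no limit on the fold. Named genes were chosen by a rule fixed before the data were examined. It takes Atg5 and Acly, the 12 largest rises and 12 largest falls with an adjusted p under 0.05, a base mean of at least 50 and a symbol that is not a predicted or clone name, up to 4 members with the smallest adjusted p in each fixed list with a call, and the 2 members of highest mean in a list without one. This named 113 genes, and results for a few of them are not reported here. Genes named outside the rule to complete small counts are stated to be so in the text and were chosen after their values were seen. Rn45s, which set the scaling to all reads, also stands outside the rule.

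Gene lists were also fixed before the data were examined. They covered autophagy machinery, autophagy receptors, lysosome, citrate and acetyl-CoA handling, TCA cycle, fatty acid synthesis, cholesterol synthesis and uptake, steroidogenesis, cumulus expansion and ovulation, granulosa identity, glycolysis, nuclear OXPHOS subunits, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, NRF2 targets, unfolded protein and integrated stress response, p53 targets, interferon response, inflammatory and NF-kB targets, cell cycle and proliferation, extracellular matrix and TGF-beta targets, immediate early and dissociation genes, and markers of oocyte, theca and stroma, leukocytes, endothelium, smooth muscle and pericytes, surface epithelium, erythroid and luteal cells. Of the 30 lists, 29 had at least 2 tested members. The list of mitochondrially encoded mRNAs matched 0 rows and was not analysed here. For a table of comparisons the plan named ranks of the deposited statistic for the list test. In a departure from it, each list was tested with camera on the deposited Wald statistics themselves, and ranks became an alternative. The test was cameraPR of limma 3.58.1 in R 4.3.3, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. These p-values set the mean statistic of a list against the other tested genes and do not measure the spread between libraries. A correlation between genes cannot be estimated from a table that pools the libraries, so a preset correlation of 0.05 was run in its place. Members called over all tested genes were counted beside those called when the deposited p was adjusted over the list alone.

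Depth was estimated from the lowest base means. Rows whose base mean is that of a single read fell on 6 steps, each with 1 fold change, which gives a size factor for each library. All 1823 rows with a base mean under 0.487 were whole numbers of reads on these steps, at a relative tolerance of 1e-06. The size factors were 1.27, 1.34 and 1.37 on the control side and 0.703, 0.784 and 0.805 on the Atg5-KD side, and which library of a group has which factor cannot be read from the table. Group means were estimated from the base mean and fold change with 3 libraries in each group. They give, rounded, 17300000 counted reads per control library and 12200000 per Atg5-KD library. The median deposited standard error of the log2 fold change was 0.15 over the tested genes and 0.13 over the 11296 with a base mean of at least 50. Intervals of 95% are the deposited log2 fold change with its standard error under the normal distribution.

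Positions come from the RefSeq annotation of GRCm38.p6, the assembly behind mm10, matched by symbol for 24417 rows. GC content and length are those of the longest transcript of each symbol in GENCODE M21, found for 14680 of the 14835 tested genes (99.0%). A trend of the log2 fold change with GC content and log length was fitted over 11234 genes with a base mean of at least 50, as a cubic polynomial (degree 3) in each with their product, by Huber robust regression, and its form was set once. Removing it gave a second set of fold changes with the deposited standard errors. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 (robust regression) and matplotlib 3.10.9 were used.

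Steps were tested on simulated data. The deposited standard errors of the 14835 genes for the comparison of Atg5-KD with control were used. Of 100 genes changed by 1 on the log2 scale 98% were called, and of 100 changed by 0.5 50%, against 0.0683% of unchanged genes. The changed genes were drawn from those with a base mean of at least 50, so lower ones were not covered. They were far fewer than the 3100 called in the deposited table, so these shares do not carry over to it directly. With the fitted trend added to unchanged genes, 455 of 14680 were called before its removal and 0 after it. The added trend had the model's own form, so this checks the procedure and not whether that form suits the data. In simulated statistics with no effect, 0 of 29 lists were called, and 2 of 2 shifted lists were called in their direction. Simulated genes were drawn independently, so these runs do not cover correlation between genes.

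Alternatives planned before the data were examined and run were no filter on base mean, a fold of at least 2 and an adjusted p under 0.01. Ranks of the statistics, the planned form of the list test, were run as an alternative too. Alternatives added after the data were seen were a base mean of at least 50, scaling to the estimated total of all reads, centring on the median and removal of the trend. For the lists, a preset correlation of 0.05 and leaving out members that another list holds were also added then. Scaling to all reads shifts every log2 fold change by -0.30. Gene families in the closing section were chosen after their values were seen and are given as counts, because a test on families chosen for their values cannot speak for the pattern. They were also counted without members of a fixed list, an alternative added after the data were seen. Genes with near-identical copies, such as Ifit3 and Ifit3b or Apol9a and Apol9b, share reads in ways the table does not show and are uncertain singly, as are genes that overlap others, since the strand setting is not given in the sources used here.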

Results

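Cumulus granulosa cells surround the oocyte, feed it through gap junctions and are ovulated with it. Transcripts of such cells from Kun-Ming mice, an outbred stock, were compared between 3 libraries labelled control and 3 libraries labelled Atg5-KD. Atg5 encodes a protein required to attach LC3 to the membrane of the forming autophagosome, and the series title places the comparison in a study of how autophagy of ATP citrate lyase bears on citrate and on maturation of the oocyte. The question addressed is which transcripts differ when Atg5 is targeted by short hairpin RNAs. Values come from the authors' deposited table of size-factor normalized base means, log2 fold changes with standard errors and Wald tests with Benjamini-Hochberg adjusted p-values, which holds 14835 tested genes and no values per library. Estimated depth, rounded, was 17300000 counted reads per control library and 12200000 per library labelled Atg5-KD.

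Atg5 itself did not pass the test between the libraries labelled Atg5-KD and control. Its log2 fold change in the authors' deposited table was -0.06 with a standard error of 0.14 (Wald adjusted p = 0.822), at a base mean of 405 normalized counts. Estimated group means from the authors' deposited table were 414 normalized counts in control and 397 in the libraries labelled Atg5-KD. The 95% interval of the log2 fold change from the authors' deposited table ran from -0.34 to 0.21, so a fall of more than 20.7% lies outside it. Scaled to the estimated total of all reads, those of the ribosomal RNA locus Rn45s included, the log2 fold change was -0.36 (adjusted p = 0.0269, Benjamini-Hochberg on shifted Wald statistics). Values of Atg5 in each library were not analysed here. Atg5 (gene 11793) lies on chromosome 10 from 44268322 to 44364299 of GRCm38.p6. As deposited, the transcript level of the target gave no check of the labels or of the direction of the fold changes, and the fall called when scaled to all reads rests on that scaling. The direction was read from the order of the groups in the table's name. If that order were turned, each rise in this text would be a fall, each fall a rise, and each value of a group would belong to the other group.

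Genes of the interferon response rose most, with the direction read in this way. Of 35 tested members of that list, 34 were higher in the libraries labelled Atg5-KD in the authors' deposited table, both over all tested genes and adjusted over the list alone, with a median log2 fold change of 3.80, a 13.9-fold difference (camera adjusted p = 2.15e-142). The remaining member was Irf1, named after its value was seen, at 0.07. Among the 12 largest rises, 10 belonged to this list. Ifi44, an interferon-induced gene on chromosome 3 from 151730922 to 151749910, had the largest log2 fold change of the named genes in the authors' deposited table, 7.49 with a standard error of 0.58 (Wald adjusted p = 9.21e-36). The authors' deposited table gave 6.89 ± 0.37 (SE) for Ifit1, which binds foreign RNA, and 6.53 ± 0.63 (SE) for Isg15, a ubiquitin-like modifier. For Usp18, the protease that removes Isg15 from its targets, the value in the authors' deposited table was 5.89 ± 0.26 (SE). Irf7, a transcription factor that amplifies interferon production, stood at 5.39 ± 0.25 (SE) and Cxcl10, a chemokine, at 5.08 ± 0.29 (SE) in the authors' deposited table. Ddx58, a cytosolic sensor of viral RNA, was 8.71-fold higher and the antiviral gene Oasl2 11.4-fold higher in the authors' deposited table. Rsad2, Mx2, Ifit3 and Oasl1 rose by between 31.7-fold and 78.3-fold in the authors' deposited table, Mx2 being annotated by RefSeq as a transcribed pseudogene in the reference strain. Outside the list, the authors' deposited table gave log2 fold changes of 5.46 for Ddx60 and 5.14 for Apol9a, both among the 12 largest rises. Inflammatory and NF-kB targets as a list were not called (camera adjusted p = 0.352), with 4 of 19 higher in the authors' deposited table and 1 lower, the same counts adjusted over the list alone. The 4 were Il6 at 1.72, Ccl7 at 1.45, Lif at 0.80 and Saa3 at 0.66 in the authors' deposited table, and the 1 lower was Cxcl5 at -0.71, named after its value was seen. Il6 and Ccl7 had low base means of 13.0 and 17.4, with standard errors of 0.61 and 0.52. With all reads as the scale, 33 interferon genes were higher and 0 lower, and 2 inflammatory genes higher and 5 lower.

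**Figure D1:**
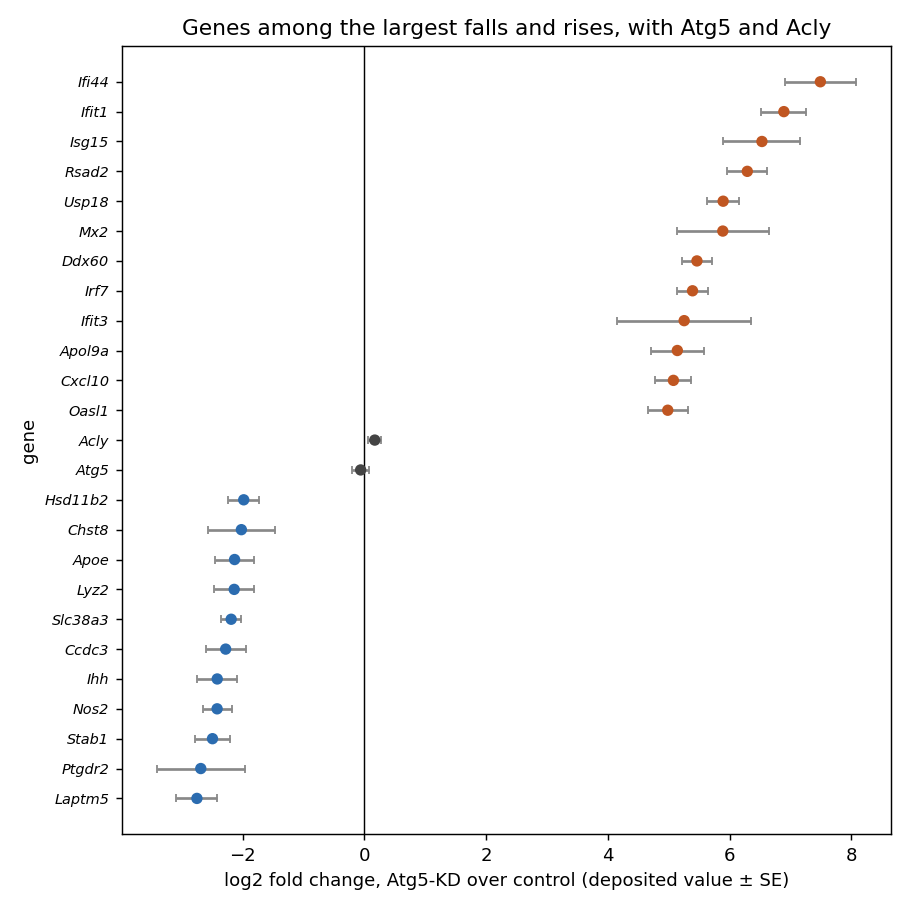
Log2 fold change in the authors' deposited table (horizontal axis, libraries labelled Atg5-KD over control) of the 12 largest rises (orange), genes among the largest falls (blue), Atg5 and Acly (dark grey), with 1 gene per line on the vertical axis, where points are deposited values and bars their standard errors. The rises run from 4.98 (Oasl1) to 7.49 (Ifi44) and the falls from -1.98 (Hsd11b2) to -2.75 (Laptm5), while Atg5 at -0.06 and Acly at 0.17 lie near 0.

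Markers of leukocytes fell. Of 20 tested, 12 were lower in the authors' deposited table (15 adjusted over the list alone) with a median log2 fold change of -1.61 (camera adjusted p = 5.35e-09), and the other 8 did not pass the test. In the authors' deposited table, C1qc and C1qa, subunits of a complement component made by macrophages, stood at -3.66 ± 0.51 (SE) and -3.06 ± 0.45 (SE) with base means of 38.3 and 44.4. The 12 largest falls included 2 of these markers. Laptm5, a lysosomal membrane protein of blood cells on chromosome 4 from 130912890 to 130936148, fell 6.73-fold in the authors' deposited table (Wald adjusted p = 2.4e-14). Lyz2, the lysozyme of myeloid cells, fell 4.40-fold in the authors' deposited table, with a base mean over both groups of 906. Further falls in the authors' deposited table were Stab1, a scavenger receptor of macrophages, at -2.49 ± 0.29 (SE), and Nos2, the inducible nitric oxide synthase, at -2.42 ± 0.24 (SE). Ihh, a hedgehog ligand that granulosa cells secrete, was at -2.42 ± 0.33 (SE), and Slc38a3, an amino acid transporter of cumulus cells, at -2.19 ± 0.16 (SE) in the authors' deposited table. Apoe, which carries lipids, and Hsd11b2, which inactivates glucocorticoids, fell 4.38-fold and 3.95-fold in the authors' deposited table. Ptgdr2 at -2.69, Ccdc3 at -2.28 and Chst8 at -2.02 were also among the 12 in the authors' deposited table.

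Genes of the extracellular matrix fell together with markers of stroma and smooth muscle. Of 30 matrix and TGF-beta target genes tested, 20 were lower and 1 higher in the authors' deposited table (21 and 1 adjusted over the list alone), with a median log2 fold change of -0.52 (camera adjusted p = 2.19e-13). The higher member was Timp1, an inhibitor of matrix proteases, at 0.53, named after its value was seen. In the authors' deposited table, Acta2 and Tagln, contractile proteins, fell 2.25-fold and 2.40-fold, Lox, which cross-links collagen, fell 2.18-fold, and Col1a1 fell 2.14-fold. Among smooth muscle and pericyte markers 9 of 11 were lower and 1 higher in the authors' deposited table (10 and 1 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 1.41e-09). Actg2 stood at -1.39 ± 0.14 (SE) and Mcam at -0.93 ± 0.13 (SE), and the higher member was Notch3 at 0.90, named after its value was seen, in the authors' deposited table. Of 14 theca and stroma markers 8 were lower, among them Col1a2 at -0.89 and Ogn at -0.90, and 1, the steroid carrier Star, was higher in the authors' deposited table (11 and 1 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 0.000882). These lists share members, since Acta2, Tagln and some collagens stand in more than 1 of them, and each call held without the shared members. Endothelial markers were not called, with 0 of 11 past the Wald test in the authors' deposited table (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05) and a camera adjusted p of 0.604. Their most abundant members, Egfl7 and Eng, stood at 0.28 ± 0.27 (SE) and -0.54 ± 0.26 (SE) in the authors' deposited table. For the matrix list 25 members were lower and 0 higher when scaled to all reads, for smooth muscle 10 and 1, for theca and stroma 12 and 1, and for endothelium 1 and 0.

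Cholesterol synthesis and steroidogenic genes rose. Of 26 genes of cholesterol synthesis and uptake, 16 were higher in the authors' deposited table (17 adjusted over the list alone) with a median log2 fold change of 0.53 (camera adjusted p = 5.63e-11), and the other 10 did not pass the test. Idi1, an isomerase of isoprenoid synthesis, rose 2.43-fold, Hmgcs1 1.87-fold and Cyp51 1.74-fold in the authors' deposited table. Of 17 steroidogenic genes 9 were higher and 2 lower in the authors' deposited table, the same adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.57e-06). Star, which brings cholesterol into mitochondria, was at 1.42 ± 0.14 (SE), Cyp11a1, the side-chain cleavage enzyme, at 1.12 ± 0.12 (SE), and its electron donor Fdx1 at 1.39 ± 0.13 (SE) in the authors' deposited table. Lhcgr, the receptor of luteinizing hormone, rose 5.11-fold in the authors' deposited table, with a base mean over both groups of 157. The 2 lower members, named after their values were seen, were Hsd17b1 at -0.79 and Nr5a1 at -0.25 in the authors' deposited table. Luteal markers, 8 of whose 15 members stand in another list, were higher in 12 cases and lower in 1 in the authors' deposited table (13 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 7.66e-13). Prlr, the prolactin receptor, was at 1.52 ± 0.14 (SE), and the lower member was Apoe at -2.13 in the authors' deposited table. Without the members shared with other lists, the luteal and cholesterol calls held and the steroidogenic call ended (camera adjusted p = 0.152). That setting left out 11 of the 17 steroidogenic genes, Star, Cyp11a1 and Lhcgr among them, and tested the other 6. The medians were smaller when scaled to all reads, 0.23 for cholesterol genes (10 higher and 1 lower), 0.08 for steroidogenic genes (7 and 3) and 0.33 for luteal markers (10 and 1). Fatty acid synthesis was higher in 7 of 22 genes in the authors' deposited table, the same adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.0155) that became -0.19 when scaled to all reads, with 5 higher and 7 lower. Me1, which makes NADPH, rose 1.83-fold, the desaturase Scd1 1.77-fold, Acsl4 1.68-fold and Elovl6 1.62-fold in the authors' deposited table. The fatty acid call was lost on the planned ranks of the statistics (camera adjusted p = 0.128). It was also lost with a preset correlation of 0.05 (camera adjusted p = 0.0873) and without shared members (camera adjusted p = 0.0977).

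Acly, the ATP citrate lyase transcript, did not pass the test. Its log2 fold change in the authors' deposited table was 0.17 with a standard error of 0.10 (Wald adjusted p = 0.252) at a base mean of 5177 normalized counts, and it became -0.13 when scaled to all reads. Acly (gene 104112) lies on chromosome 11 from 100476352 to 100528000 of GRCm38.p6. The list of citrate and acetyl-CoA handling was not called (camera adjusted p = 0.344), with 5 of 19 members higher and 2 lower in the authors' deposited table (5 and 3 adjusted over the list alone). Me1, Idh1 at 0.49, Acaca at 0.57, Acat2 at 0.53 and Aco1 at 0.31 were the higher members in the authors' deposited table, and Pdk2 at -0.42 was among the lower ones, where Aco1 and Pdk2 were named after their values were seen. The median of this list was -0.01, its mean 0.07 and the direction of its test upward, and scaled to all reads 1 member was higher and 11 were lower. In the TCA cycle 3 of 19 genes, among them Idh2 at -0.43 and Idh3g at -0.41, were lower in the authors' deposited table, the same adjusted over the list alone (camera adjusted p = 0.163). For nuclear OXPHOS subunits 0 of 43 passed the Wald test in the authors' deposited table or adjusted over the list alone, with 1 higher and 8 lower at an unadjusted p under 0.05 (camera adjusted p = 0.137). The most abundant, Atp5b and Atp5a1, stood at -0.09 ± 0.10 (SE) and -0.15 ± 0.08 (SE) in the authors' deposited table. In glycolysis Hk2, a hexokinase, rose 1.66-fold while Pfkl, Gpi1, Slc2a1 and Pkm fell by 0.38, 0.34, 0.38 and 0.26 on the log2 scale among 17 genes in the authors' deposited table (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0912), Pkm being named after its value was seen. Of the TCA cycle 15 genes, of OXPHOS 34 and of glycolysis 14 were lower when scaled to all reads, with 0, 0 and 1 higher, and these 3 lists were then called lower. That scaling called 5735 of all 14835 tested genes lower. Its constant shift moves the statistics of genes with small standard errors most, so these list calls may follow from it. On ranks of the deposited statistics, with no shift, glycolysis and OXPHOS were also called lower (camera adjusted p = 0.00721 and 0.0173). The TCA cycle was not called on ranks (camera adjusted p = 0.0861). With the trend in GC content and length removed, the 3 lists had 1, 0 and 1 lower and 0, 0 and 1 higher members. None was then called (camera adjusted p = 0.2365, 0.6178 and 0.6178).

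The autophagy machinery beyond Atg5 was not called as a list. Of 36 genes 2 were higher and 5 lower in the authors' deposited table, the same adjusted over the list alone (camera adjusted p = 0.939), with a median and mean of 0.01 and a test direction downward. Scaled to all reads, which shifts every log2 fold change by -0.30, 0 were higher and 19 lower with a median of -0.29. Rb1cc1, part of the kinase complex that starts autophagy, was at 0.48 and Atg2b at 0.36 in the authors' deposited table. Lower were the LC3 genes Map1lc3b at -0.32 and Map1lc3a at -0.39, with Atg9a at -0.35, Wipi1 at -0.29 and Gabarapl1 at -0.28 in the authors' deposited table, where Atg2b, Wipi1 and Gabarapl1 were named after their values were seen. Once the trend with GC content was removed, 1 of the 36, Map1lc3b, was called. Of 16 autophagy receptors, Ncoa4 at 0.49, Nbr1 at 0.38 and Sqstm1, the p62 receptor, at 0.34 ± 0.10 (SE) were higher and Phb2 at -0.32 lower in the authors' deposited table, the same adjusted over the list alone (camera adjusted p = 0.394). Lysosomal genes had 6 of 41 members higher and 8 lower in the authors' deposited table (6 and 9 adjusted over the list alone, camera adjusted p = 0.371). Once the trend was removed 1 lysosomal gene was higher and 1 lower (camera adjusted p = 0.963). With the scaling to all reads 0 were higher and 28 lower, and the list was called lower, while for the autophagy receptors 0 were higher and 6 lower. Ctss, a protease abundant in macrophages, fell 2.40-fold and Ctsf 1.37-fold, while Npc2 and Atp6v1h rose by 0.38 and 0.41 on the log2 scale in the authors' deposited table.

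Granulosa identity genes fell more often than they rose. Of 26, 12 were lower and 5 higher in the authors' deposited table (13 and 6 adjusted over the list alone), with a median log2 fold change of -0.26 (camera adjusted p = 0.00245, and 0.0731 on ranks of the statistics). Serpine2 fell 1.85-fold and Inhbb, a subunit of activin B and inhibin B, fell 2.20-fold in the authors' deposited table. The higher members were Nr5a2 at 0.62, Nppc, whose peptide holds the oocyte in meiotic arrest, at 1.24, Kitl at 0.78, Inhba at 0.45 and Cdh2 at 0.28 in the authors' deposited table, of which Nr5a2 alone was named by the rule and the others after their values were seen. The value of Nppc rests on few reads, with a base mean of 19.7, a standard error of 0.48 and a Wald adjusted p of 0.0469. Genes of cumulus expansion and ovulation were not called as a list (camera adjusted p = 0.344), with 6 of 23 higher and 3 lower in the authors' deposited table (7 and 3 adjusted over the list alone). Vcan, a matrix proteoglycan, rose 2.65-fold, Adamts1, the protease that cleaves it, 1.99-fold and Runx2 1.53-fold in the authors' deposited table. The lower ones were Itih5 at -1.90, and, named after their values were seen, Cebpa at -0.50 and Ptger2 at -0.47 in the authors' deposited table. Immediate early and dissociation genes were not called either (camera adjusted p = 0.214), with 2 of 24 higher and 4 lower in the authors' deposited table (3 and 4 adjusted over the list alone). Fos fell 2.65-fold and Klf2 2.25-fold, Socs3 and Egr1 stood at -0.70 and -0.56, and Btg2 and Klf6 at 0.73 and 0.46 in the authors' deposited table, where Socs3 and Egr1 were named after their values were seen. Oocyte markers had 1 of 12 members higher, Tle6 at 0.66, surface epithelium 1 of 12 lower, Cldn3 at -0.74, and the erythroid list 1 of 2 higher, Alas2 at 1.96, in the authors' deposited table (camera adjusted p = 0.519, 0.371 and 0.352). Adjusted over the list alone these counts were 1, 0 and 1. Granulosa identity had 2 higher and 17 lower members when scaled to all reads, cumulus expansion and ovulation 5 and 7, immediate early and dissociation genes 1 and 13, oocyte markers 0 and 0, surface epithelium 0 and 6, and the erythroid list 1 and 1.

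Genes of the unfolded protein and integrated stress response fell. Of 28, 12 were lower and 1 higher in the authors' deposited table (16 and 2 adjusted over the list alone), with a median log2 fold change of -0.25 (camera adjusted p = 0.000173). In the authors' deposited table Hyou1 and Pdia6, chaperones of the endoplasmic reticulum, were both at -0.42 ± 0.09 (SE), Nupr1 was at -0.85 ± 0.14 (SE), and the higher member, the stress transcription factor Ddit3, was at 0.66 ± 0.15 (SE). Cytosolic ribosomal protein genes were lower in 11 of 40 cases in the authors' deposited table (12 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.000123). Rps2, Rplp0, Rpl10a and Rpsa stood between -0.48 and -0.35 in the authors' deposited table, and 5 of the 40 were called once the trend with GC content and length was removed. Cell cycle genes were lower in 6 of 36 cases in the authors' deposited table, the same adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0181, and 0.141 with a preset correlation of 0.05). Aurkb, Cdc20, Mcm6 and Plk1 were at -0.54, -0.45, -0.40 and -0.38 in the authors' deposited table. p53 targets were not called (camera adjusted p = 0.0912, and 0.0224 once the trend was removed), with 7 of 20 higher and 2 lower in the authors' deposited table, the same adjusted over the list alone. Among them Btg2, Trp53inp1, Eda2r and Ccng1 were at 0.73, 0.62, 0.60 and 0.48 in the authors' deposited table, while the lower members, Perp at -0.59 and Plk2 at -0.38, were named after their values were seen. The median of the p53 list was -0.01, its mean 0.11 and the direction of its test upward. NRF2 targets were not called (camera adjusted p = 0.163), with Osgin1, raised 3.07-fold, Hmox1, raised 1.41-fold, Me1 and Txnrd1 higher and Gclc, 1.28-fold lower, among 22 genes in the authors' deposited table, the same adjusted over the list alone, Txnrd1 being named after its value was seen. The lower members numbered 25 for the stress response, 37 for ribosomal proteins and 29 for the cell cycle when scaled to all reads, with medians of -0.55, -0.51 and -0.46, and p53 targets had 3 higher and 7 lower members and NRF2 targets 2 and 10.

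**Figure D2:**
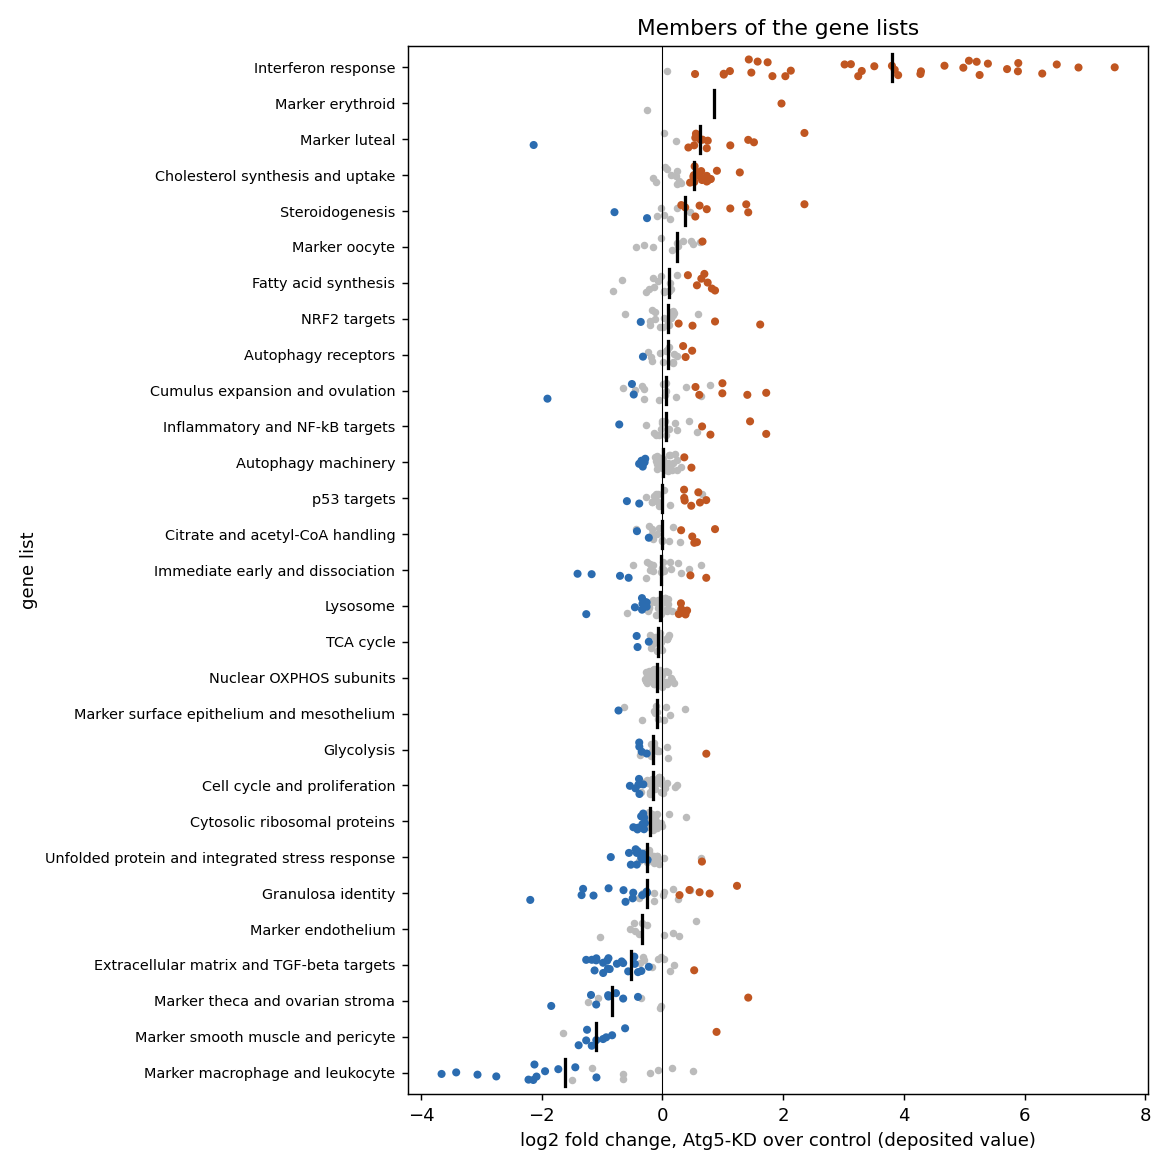
Log2 fold change in the authors' deposited table (horizontal axis, libraries labelled Atg5-KD over control) of each tested member of the 29 gene lists (vertical axis, 1 list per line), with members past an adjusted p of 0.05 in orange (higher) or blue (lower), the others in grey, and the median of each list as a black bar. The interferon list has its median at 3.80 and the leukocyte markers at -1.61, and both keep their direction when scaled to all reads.

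Over all tested genes, 1541 were higher and 1559 lower in the libraries labelled Atg5-KD, 20.9% of 14835 by the Wald test in the authors' deposited table. Scaled to the estimated total of all reads the split moved from 49.7% to 8.52% of calls higher, with 534 genes higher and 5735 lower. The difference between both scalings was set by Rn45s, a ribosomal RNA locus whose reads were not split into precursor and mature RNA. Its log2 fold change in the authors' deposited table was 4.24 ± 0.32 (SE) at a base mean of 1509950. The log2 ratio of the summed normalized counts was 0.30 with this gene and 0.03 without it. Its estimated share of counted reads was 1.17% in control and 17.9% in the libraries labelled Atg5-KD, or the other way round if the direction were turned. Fold changes also followed base composition. Across 11234 genes with a base mean of at least 50, which are not independent replicates, Spearman's rho of the log2 fold change in the authors' deposited table was -0.46 with the GC content of the transcript and 0.28 with its length. The median log2 fold change in the authors' deposited table was 0.21 in the decile of genes lowest in GC and -0.24 in the decile highest in GC. With this trend removed, 932 genes were higher and 1075 lower, and 1663 of the 3100 deposited calls held in the same direction. Once the trend was removed, 100% of the 34 called interferon genes kept their call, and the lists of leukocyte markers, cholesterol genes and luteal markers counted 12 lower, 17 higher and 12 higher members. Among 107 called genes named by the rule, 15 lost their call without the trend, among them Rb1cc1, Map1lc3a, Atg9a, Phb2, Ctsf, Atp6v1h, Idh2, Pfkl, Slc2a1, Rpsa, Il6, Cdc20, Plk1 and Cldn3. Scaled to all reads, 15 lost it, namely Rb1cc1, Ncoa4, Nbr1, Sqstm1, Atp6v1h, Npc2, Idh1, Acaca, Acat2, Hmox1, Ccng1, Ccl7, Saa3, Tle6 and Klf6.

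**Figure D3:**
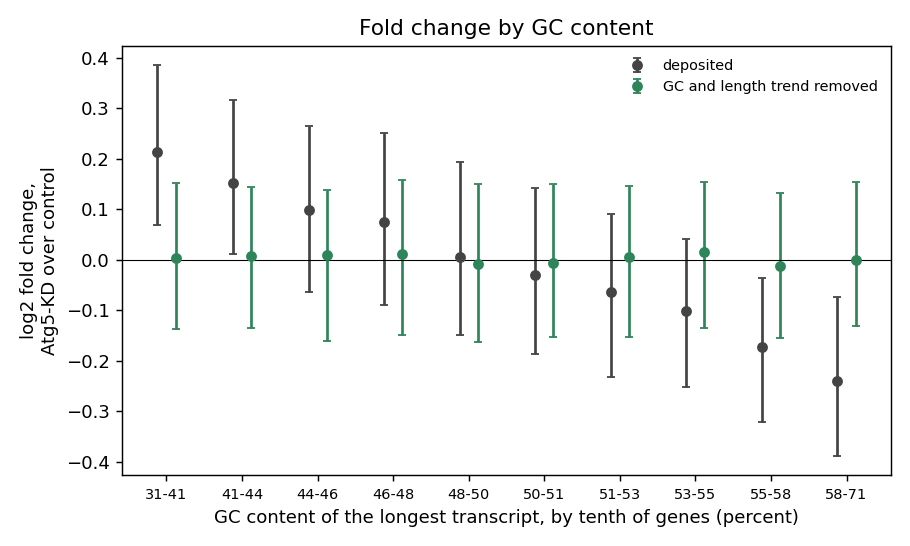
Median log2 fold change (vertical axis, libraries labelled Atg5-KD over control) in deciles of genes by GC content of the longest transcript in percent (horizontal axis), with bars from the lower to the upper quartile, for the authors' deposited table (dark grey) and once the trend with GC content and length was removed (green). The deposited medians fall from 0.21 in the lowest decile to -0.24 in the highest, and the medians without the trend stay between -0.01 and 0.01.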

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

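Both tests named here were written before the values they measure were seen, except for the bootstrap interval of the non-coding RNAs, which was added after their median was seen.

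Rn45s, a ribosomal RNA locus, stood out in libraries whose labels give poly(A) RNA as the molecule, a kind of library not made to measure it. Its reads cannot be split here into precursor and mature ribosomal RNA. The protocol names total RNA as the input, and how or whether poly(A) RNA was selected is not given in the sources used here. What the share of reads of Rn45s means is therefore uncertain. Its log2 fold change in the authors' deposited table was 4.24 ± 0.32 (SE, Wald adjusted p = 2.55e-37), from an estimated 1.17% of counted reads in control to 17.9% in the libraries labelled Atg5-KD, or the other way round if the direction of the fold changes were turned. In the authors' deposited table Lars2 rose by 3.39 and Mir6236 by 3.24 on the log2 scale, both chosen after their values were seen. The fold changes of other genes followed the GC content of their transcripts at the same time (Spearman's rho of -0.46 across genes).

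A lower depth on the Atg5-KD side, where size factors average 0.764 against 1.33 in control, would leave a trend mainly in genes with few reads. Among 3273 genes with a base mean of 1000 or more, rho with GC content was -0.52 across genes, which argues against depth as the source of the trend. More nuclear or unprocessed RNA in the libraries labelled Atg5-KD could raise reads of the ribosomal RNA locus and long non-coding RNAs together. The 134 long non-coding RNAs with a base mean of at least 50 had a median of 0.1005 once the trend was removed, just past the preset bound of 0.1 that favours this explanation, but with quartiles of -0.10 and 0.36 and a bootstrap interval of the median from 0.03 to 0.18 (10000 resamples) that spans the bound, so it was left open. A difference in poly(A) selection or in library making between the groups, and an effect of targeting Atg5 on ribosomal RNA, were not tested and cannot be separated in a table that pools the libraries of each group.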

How the results depend on the processing

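Scaling, centring, the trend, a base mean of at least 50 and all settings of the list test except no filter and ranks were added after the data were seen. Ranks were the planned form of the list test, from which the main test departed. Scaled to all reads, 534 genes were higher and 5735 lower, Atg5 was at -0.36 (adjusted p = 0.0269) and Acly at -0.13, against 1541, 1559, -0.06 and 0.17 as deposited. The shift of -0.30 in every fold change, set by Rn45s, is the cause. With the trend removed 932 genes were higher and 1075 lower, and 1663 of 3100 calls were shared, 0 in the opposite direction. A fold of at least 2 left 332 higher and 281 lower and an adjusted p under 0.01 left 1026 and 1030, both stricter by construction. Adjusted p ranged from 0.0269 to 0.886 for Atg5 and from 0.176 to 0.331 for Acly. Lists called numbered 13 as tested and from 11 to 16 over 8 alternatives. Calls were lost for fatty acid synthesis (preset correlation of 0.05, ranks, all reads, shared members left out), cell cycle (0.05), granulosa identity (ranks) and steroidogenesis (shared members left out), and gained for p53 targets (trend), glycolysis and OXPHOS (ranks, all reads), and lysosome and TCA cycle (all reads), and the causes were not tested. For calls gained under all reads, the constant shift by construction lowers the statistics of genes with small standard errors most. Oocyte and erythroid lists have no value at a base mean of at least 50. Of 107 called named genes, 15 lost their call with the trend removed, 15 scaled to all reads, 1 centred and 1 with no filter, and 0 reversed. No paired analysis was possible because the table gives no values per library, although the groups share the numbers 2, 3 and 4. For the same reason other normalizations, other tests, filters on counts, pseudocounts, leaving out a replicate, fry, an estimated correlation, library structure and other splits of the 6 libraries were not run, so chance in the grouping was not tested. A standard error of 0.13, the median at a base mean of at least 50, limits what single genes can show.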

Other observations

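The gene families below, and the tests on leukocytes, on hairpin delivery, on the precision and the scaling of Atg5 and on exchanged labels, were chosen only after the values were seen.

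Some families of defence genes held many higher members and some families of matrix and signalling genes many lower ones. Because the families were picked for their values, they are given as counts without a test, beside 10.4% of all tested genes higher and 10.5% lower in the authors' deposited table. Of 12 guanylate-binding proteins and immunity-related GTPases 11 were higher in the authors' deposited table, Irgm1 at 2.34 ± 0.12 (SE), and without the 3 that the interferon list holds 8 of 9. MHC class I genes, of which that list holds 0, were higher in 8 of 15 cases in the authors' deposited table, H2-K1 at 1.35 and H2-D1 at 1.69, and some of these genes are near-identical. PARP genes were higher in 6 of 12 cases in the authors' deposited table, with Parp9 at 2.72, and in 5 of 11 without the 1 in the interferon list, while scaled to all reads 4 of the 12 were higher and 2 lower with a median that went from 0.35 to 0.05. TRIM genes were higher in 13 of 46 cases and lower in 3 in the authors' deposited table, with Trim25, which activates the RNA sensor Ddx58, at 0.96, and scaled to all reads they were higher in 9 and lower in 11 with a median that turned from 0.13 to -0.17. Collagens were lower in 15 of 38 cases and higher in 2 in the authors' deposited table, Col11a1 at -1.19, and without the 10 that the matrix list holds 8 of 28 were lower and 2 higher with a median of -0.08. Once the trend was removed 8 of these 28 were lower and 5 higher, and scaled to all reads 11 and 0. Of 6 bone morphogenetic proteins, leaving out the protease Bmp1, which shares only the name, 3 were lower in the authors' deposited table, Bmp3 at -1.87 ± 0.15 (SE), Bmp2 at -1.10 and Bmp6 at -1.34. When scaled to all reads 6 of the 6 were lower, and their median went from -1.22 to -1.52. Matrix metalloproteinases were lower in 6 of 12 cases, tubulins in 7 of 12 and myosin light chains and tropomyosins in 5 of 11 in the authors' deposited table, 5, 4 and 5 were called lower with the trend removed, and 4 of 10 metalloproteinases were lower without those in the matrix list. When scaled to all reads 8, 10 and 8 members of these 3 families were lower, beside 5735 of all 14835 tested genes. Genes with ADAMTS or ADAMTS-like symbols were lower in 6 of 18 cases and higher in 2 in the authors' deposited table. Both higher ones stand in the list of cumulus expansion and ovulation. Of the 18, 5 were lower and 3 higher with the trend removed and 8 and 1 when scaled to all reads. In that scaling 11 of the GTPases were higher and 0 lower, and MHC class I genes had 7 higher and 1 lower.

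Of 8 long non-coding RNAs with a base mean of at least 1000, 4 were higher in the authors' deposited table and 4 did not pass the test. Malat1 was at 1.82 ± 0.13 (SE), Neat1 at 0.99 ± 0.11 (SE) and Kcnq1ot1 at 2.02 ± 0.29 (SE) in the authors' deposited table, all higher when scaled to all reads too, and 1.56, 0.52 and 0.47 once the trend was removed, where Kcnq1ot1 no longer passed the test (adjusted p = 0.335). Tug1, at 0.30 ± 0.10 (SE) in the authors' deposited table, was at -0.03 once the trend was removed and near 0 when scaled to all reads. Xist at 0.62 ± 0.26 (SE), Firre at 0.10, Gas5 at -0.07 and Foxl2os at -0.19 were the others in the authors' deposited table. Long non-coding RNAs as a class were higher in 70 of 727 cases and lower in 9 in the authors' deposited table, beside 10.4% and 10.5% of all tested genes. The share higher was thus near that of all genes, and falls were few. Once the trend was removed 48 were higher and 6 lower, and the medians were 0.23 as deposited and 0.24 without the trend. For the 134 with a base mean of at least 50 both medians were 0.10. When scaled to all reads 53 of the 727 were higher and 50 lower, and their median turned to -0.07. Zinc finger genes were higher in 57 of 367 cases and lower in 18 in the authors' deposited table, with 12 and 8 called once the trend was removed, and when scaled to all reads 8 were higher and 72 lower with a median that turned from 0.19 to -0.10. Small nucleolar RNAs had 0 of 65 past the Wald test in the authors' deposited table, with 2 higher at an unadjusted p under 0.05.

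The rise of interferon genes has technical and biological explanations. A larger share of leukocytes where interferon genes are higher is argued against by their markers, 0 of which stand in another list. Their median was -1.61 in the authors' deposited table with an upper quartile of -0.66, and their most abundant fallen member Lyz2 was at -2.14. An interferon response within the leukocytes that remained was not tested. The trend with GC content and length does not account for the rise, since 100% of the called members stayed past the threshold without the trend. Delivery of the hairpins, as double-stranded RNA that sensors such as Ddx58 read, may raise all 34 called members by itself. It cannot be told apart from an effect of targeting Atg5, because both would come in the same libraries and the labels do not say what the control cells received. The Atg5 transcript was at -0.06 ± 0.14 (SE, Wald adjusted p = 0.822) in the authors' deposited table, so a loss of Atg5 is itself not shown there. Loss of Atg5 as the cause stays an open hypothesis.

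The Atg5 transcript did not pass as lower in the libraries labelled Atg5-KD in the authors' deposited table, while scaled to all reads it did, at -0.36 (adjusted p = 0.0269, against 0.731 to 0.886 in the other alternatives). A fall by 1 on the log2 scale that was measured imprecisely is argued against by the lower bound of the 95% interval from the authors' deposited table, -0.34. Removing the trend left the lower bound at -0.38, and scaling to all reads left it at -0.63. Exchanged labels of the groups cannot be told apart from correct ones by the authors' deposited table, because its interval from -0.34 to 0.21 holds 0 and reaches neither a fall nor a rise by 1. Scaled to all reads the interval ran from -0.63 to -0.09, below 0 as the labels have it, but that rests on the shift of -0.30 set by Rn45s and does not reach a fall by 1 either. A small fall, a loss of protein with little change of the transcript, and wrong labels of single libraries may each remain, and none of these was decided here.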
